A study of Mus musculus with 6 samples.

How the data were processed

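Gene symbols and inclusion frequencies of alternative splicing events were analysed for 6 RNA sequencing libraries of primary mouse medullary thymic epithelial cells. The libraries formed 3 groups of 2. The control group (Ctr) carried an shRNA against LacZ, and the knockdown groups carried shRNAs against Raver2 or Setd2, with a different hairpin in each of the 2 libraries of a target. Per the labels' protocols, the cells grew in an organotypic co-culture and were collected 5 days after infection by sorting for viability, MHC class II and GFP. Total RNA was amplified with a SMART-seq kit for low RNA input, and libraries were made with a transposase kit, per the labels' protocols.

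Each value deposited by the authors was a fraction from 0 to 1, the frequency with which an event was included. Per the submitters' processing notes, Trimmomatic 0.39, TopHat2 and Cufflinks were used with the mouse genome build mm10; no role, order or setting is given for them. How the inclusion frequency was computed, which classes of event were kept and how low coverage was treated are not given in the sources used here. No read counts, coverage, event coordinates or expression levels were used here, so the depth behind each fraction is unknown. A fraction of exactly 0 or 1 can then stand for strong evidence or for a handful of reads, and the fractions alone do not tell these apart. Amplification from few cells and thin coverage can both push estimates towards 0 or 1, and such estimates can differ widely between libraries without any change in splicing.

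The tables identified events by gene symbol only. Events were therefore matched between libraries by gene and by their order within the gene, which assumes that the order is the same in every table. This was checked on genes with several events: the correlation between libraries at the same position was 0.742 to 0.802, against 0.0863 to 0.133 after shifting the order by a place. A gene entered the comparisons only if all 6 libraries listed it with the same number of events. Of 2898 genes listed in any library, 2685 genes with 4658 events met this, 213 did not, and 14 of the latter differed in their number of events. Among the genes kept, 1677 had 1 event and 1008 had at least 2, up to 15. Of the events kept, 161 held the same values in all 6 libraries as an earlier event of their gene. Gene positions were taken from the GENCODE M21 annotation of mm10 by symbol, which matched 2801 of the 2898 symbols. They locate the gene and not the event.

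The main test was limma 3.58.1 in R 4.3.3, fitted to the fractions with a mean per group over all 6 libraries, a trend of the variance with the mean fraction in the empirical Bayes step and two-sided contrasts. Benjamini-Hochberg adjustment ran over the 4658 events, with an adjusted p of 0.05 as the threshold. Library means, and the difference between events of Aire-sensitive and other genes, were compared by two-sided exact permutation of the 4 libraries concerned, where 6 assignments allow no p under 0.333. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the 15 lists of each comparison. Counts of changed events were made with adjustment over all events and over the list alone. Agreement between hairpins was measured across events with a different Ctr library subtracted from each hairpin. For the overlap between the knockdowns, which share both Ctr libraries, 100 simulations of unchanged groups gave the values expected without any effect. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

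Samples, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. For each comparison the rule named the 12 higher and 12 lower events with the largest absolute moderated t among those past the threshold, 1 event per gene, and up to 4 members of each list by absolute moderated t. Raver2, Setd2, Raver1, Ptbp1, Ptbp2 and Aire were to be named wherever listed. For Raver2 against Setd2, 1 of the higher and lower events that met the rule is left out of the text. Of the list members that met the rule, the text names only some. Genes named outside the rule are marked as chosen after their values were seen. The plan provided for classes of Aire-sensitive and neutral genes from the authors; none accompanied the fractions used here, so a textbook list of Aire-dependent antigens stood for the sensitive class and all other genes for the neutral class. The other lists held thymic epithelial regulators, MHC and antigen processing genes, hnRNP and PTB proteins, SR proteins, RNA processing genes, chromatin genes, exons linked to PTB or histone methylation, epithelial adhesion genes, cytoskeletal genes, fibroblast genes, leukocyte genes, apoptosis and DNA damage genes, translation genes, and mitochondrial and metabolic genes.

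The analysis was tested on simulated fractions with the layout of Raver2 against Ctr. In these, 200 events with means away from 0 and 1 were shifted by 0.2 or 0.4. Over 4658 events with the observed spread, the test recovered 8 of 100 events shifted by 0.4 and 0 of 100 shifted by 0.2, with 3 of 11 calls on unchanged events. Over the 2601 simulated events that stayed from 0.01 to 0.99 in every library, it recovered 41 of 73 and 14 of 78, with 2 of 57 calls on unchanged events. The data held 2000 such events, so the simulation had fewer events near 0 or 1 than the data. It does not measure recovery of events at those ends. Over all events the share of calls on unchanged events, 27.3%, was thus above the threshold. It rests on 1 simulated set with 11 calls, so it does not measure the rate of false calls. Where on the scale these calls lay is not known, and single calls over all events stay uncertain. A missing call in a design of 2 against 2 likewise does not show that an event was unchanged.

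Alternatives fixed in advance were a logit scale, an arcsine square root scale, the empirical Bayes step without trend or made robust, only the 4 libraries compared, an adjusted p of 0.1, events present in at least 1 library per group, events with a mean from 0.05 to 0.95, 1 value per gene, each library left out in turn, and the replicate number as a block. After seeing that many fractions lay at 0 or 1, further alternatives were added: events with every library from 0.01 to 0.99 (2000 events), events with at least 3 such libraries (3223), genes with 1 event, repeated events left out, and both knockdowns together against Ctr. Events of the 213 genes that were not matched entered no comparison other than the alternative with at least 1 library per group. Expression levels, and with them the extent of each knockdown, were not analysed here.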

Results

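Medullary thymic epithelial cells (mTECs) are stromal cells of the thymus that display antigens of peripheral tissues to developing T cells, largely under the control of the autoimmune regulator Aire. Primary mouse mTECs were grown with human dermal fibroblasts in a fibrin gel and infected with lentiviruses that expressed short hairpin RNAs and GFP. The hairpins were directed against Raver2, an RNA-binding partner of the splicing repressor PTB, against Setd2, a histone methyltransferase that acts along transcribed genes, or against bacterial LacZ as the control (Ctr). Infected mTECs were sorted 5 days later and their RNA was sequenced, giving 6 libraries with 2 per group. The measured quantity was the inclusion frequency of alternative splicing events, a fraction from 0 to 1, and the purpose was to learn how each knockdown alters inclusion in Aire-sensitive and neutral genes.

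The libraries listed 4777 to 4949 events in 2765 to 2857 genes, and 4658 events of 2685 genes were compared across all 6. Read counts were not part of the values, so the depth behind each fraction is unknown and no counting interval is given. Each event is known by its gene alone; which exon or splice site it concerns is not known here, and events are numbered by their order within the gene. The labels do not say whether the libraries of a group came from separate animals or cultures. The p-values therefore measure only the spread between these libraries, which may be technical in Ctr and includes the difference between hairpins in the knockdown groups.

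Neither targeted gene could be checked. Raver2 and Setd2 had no listed event in any of the 6 libraries, and inclusion frequencies carry no expression level, so the extent of each knockdown is not known from these data. Raver1, a relative of Raver2, and Ptbp2, the neuronal PTB protein, were not listed either. Ptbp1, which encodes PTB itself (chromosome 10, 79854427 to 79864771, mm10, GENCODE M21), had 2 events in all libraries. The inclusion of its event 1 was 0.305 ± 0.00281 in Ctr (SD, n = 2), 0.247 ± 0.0128 under Raver2 knockdown and 0.245 ± 0.0204 under Setd2 knockdown, and neither change passed the test (limma, adjusted p = 0.634 and 0.604). Event 2 of Ptbp1 had means of 0.926, 0.870 and 0.892 in the same order and did not pass either (adjusted p = 0.577 and 0.700). Of the markers fixed for each cell type, events were listed for 2 of 10 thymic epithelial genes (Aire and Cd74), 1 of 10 fibroblast genes (Postn) and 3 of 10 leukocyte genes (Ptprc, Cd8a and Lck); a listed event says nothing of the share of such cells.

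The spread between libraries of the same group was wide. Fractions correlated at 0.796 to 0.809 (Pearson, across events, which are not independent replicates) between libraries of the same group, at 0.789 to 0.798 between Raver2 and Setd2 libraries, and at 0.753 to 0.765 between Ctr and knockdown libraries. Within a group, 27.7% of events in Ctr, 22.9% under Raver2 knockdown and 25.5% under Setd2 knockdown differed by more than 0.1 between the 2 libraries. Many fractions lay at the ends of the scale: 2658 of the 4658 events had a fraction below 0.01 or above 0.99 in at least 1 library, and 2000 had none. The latter are called mid-range events below, a class defined after the data had been seen.

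**Figure D1:**
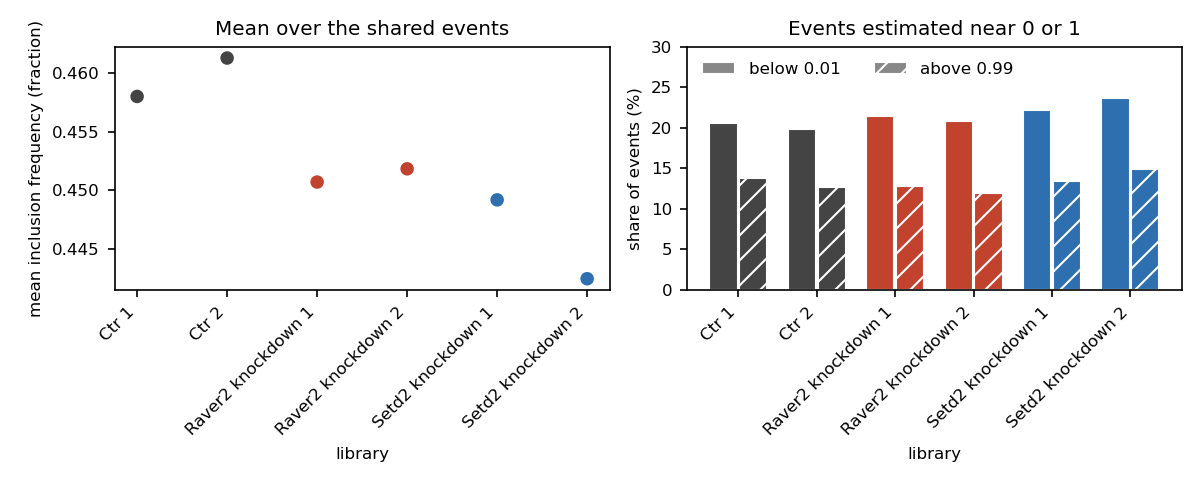
Left, mean inclusion frequency (fraction) over the 4658 shared events in each library; right, share of those events (%) with a fraction below 0.01 (plain bars) or above 0.99 (hatched bars), with Ctr in grey, Raver2 knockdown in red and Setd2 knockdown in blue. The Ctr libraries have means of 0.458 and 0.461 and the knockdown libraries lie from 0.442 to 0.452.

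Events of Aire itself passed the test in both knockdowns. The gene (chromosome 10, 78030022 to 78043610, minus strand) had 9 events. Event 1 was below 0.01 in both Ctr libraries and rose to 0.115 ± 0.01001 (SD, n = 2) under Raver2 knockdown and to 0.0761 ± 0.0119 under Setd2 knockdown (limma, adjusted p = 0.0192 and 0.0498). Event 2 of Aire rose from below 0.01 to 0.179 ± 0.0149 and 0.114 ± 0.00627 (adjusted p = 0.00820 and 0.0254). Event 3 of Aire fell from above 0.99 to 0.891 ± 0.00131 and 0.929 ± 0.00533 (adjusted p = 0.00572 and 0.0190). The other 6 events of Aire did not pass. Event 8 had means above 0.99 in Ctr, 0.874 and 0.878 (limma, adjusted p = 0.291 and 0.304). Event 7 was above 0.99 in 1 library and below 0.01 in the other within every group. Fractions of this gene at the ends of the scale can thus differ fully between libraries of a group. The change under Raver2 knockdown was the larger of the pair for events 1 to 3, but Raver2 and Setd2 knockdown did not differ by test (adjusted p = 0.482, 0.202 and 0.149). For Raver2 knockdown against Ctr, Aire events 2 and 3 passed under all 9 other settings of scale, variance model and libraries, and event 1 under 6 of 9. For Setd2 knockdown against Ctr, events 1, 2 and 3 passed under 2, 4 and 8 of 9. No event of Aire passed with both knockdowns together against Ctr, a comparison added after the data were seen.

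The comparison of Raver2 knockdown with Ctr asked which events depend on this partner of PTB. Among mid-range events, inclusion fell in Golim4, a membrane protein of the Golgi apparatus, from 0.703 ± 0.0300 (SD, n = 2) to 0.0910 ± 0.0522, a change of -0.612 ± 0.0429 (SE; limma over all events, adjusted p = 0.0184). Inclusion rose in Nhsl1, a regulator of actin at the leading edge of moving cells, from 0.381 ± 0.0533 to 0.881 ± 0.0159 (adjusted p = 0.0158). It fell in Mprip, which links myosin phosphatase to actin, from 0.499 to 0.139, in Sytl2, a vesicle trafficking protein, from 0.293 to 0.0705, in Picalm, an adaptor of clathrin-mediated endocytosis, from 0.277 to 0.0647, and in Lrrfip1, a nucleic acid-binding protein, from 0.151 to 0.0244. It rose in Eif4a2, an RNA helicase of translation initiation, from 0.574 to 0.854, in Tnip1, an inhibitor of NF-kB signalling, from 0.737 to 0.956, and in a pair of events of Bmp1, a protease that matures collagen, from 0.0655 to 0.220. Golim4 lies on chromosome 3 (75875084 to 75956949, minus strand), Nhsl1 on chromosome 10 (18318985 to 18533892), Eif4a2 on chromosome 16 (23107444 to 23114136) and Bmp1 on chromosome 14 (70474558 to 70520234, minus strand), and their exons concerned are not known here. These 10 events of 9 genes were those that passed when the 2000 mid-range events were fitted alone, and they passed over all events as well. The pair of Bmp1 events held the same values in every library, so it is a single measurement.

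**Figure D2:**
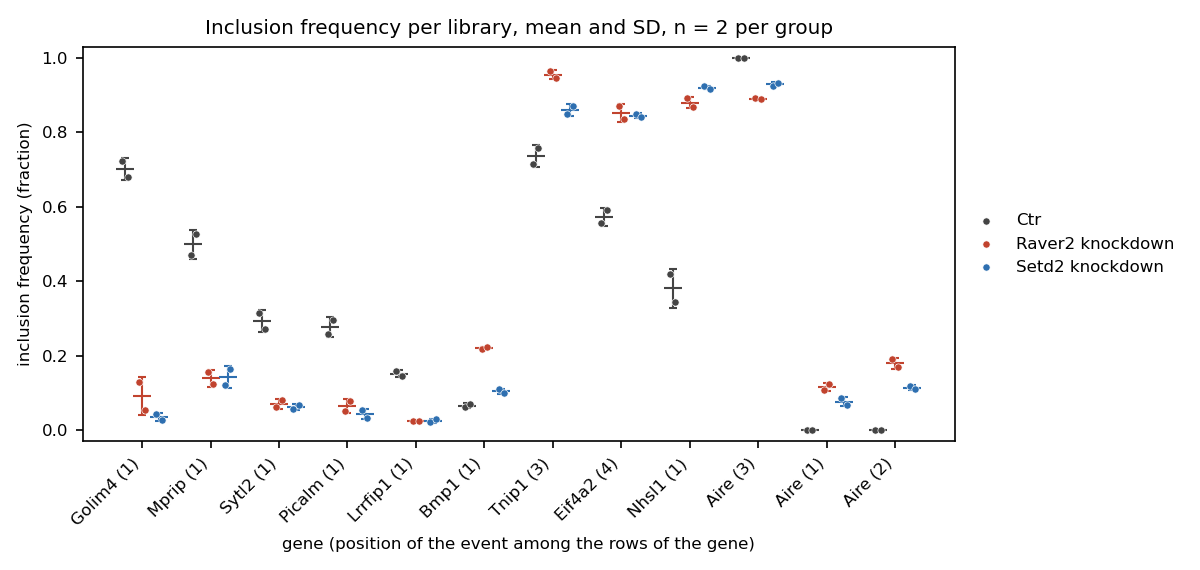
Inclusion frequency (fraction) of single events in each library (points), with the mean (horizontal line) and SD (vertical bar) of the 2 libraries of each group; numbers in parentheses give the order of the event within its gene. Event 1 of Golim4 falls from a mean of 0.703 in Ctr to 0.0910 and 0.0344, and event 2 of Aire rises from below 0.01 to 0.179 and 0.114.

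Events with a library at the end of the scale gave the largest changes. Under Raver2 knockdown, inclusion rose from below 0.01 to above 0.99 in Kng2, a kininogen gene expressed mainly in liver, and in Slc10a7, a solute carrier family member, and from 0.0355 ± 0.0119 to 0.998 in event 1 of Lin7a, a scaffold of cell polarity. It fell from 0.128 ± 0.00170 to below 0.01 in Ebf3, a transcription factor (change -0.127 ± 0.00177, SE; adjusted p = 0.00186), from 0.335 ± 0.0142 to 0.00880 in Prrx1, a homeobox factor of mesenchyme (adjusted p = 0.00369), and from 0.469 to below 0.01 in Fnbp1, which shapes membranes. Event 3 of Serpinh1, the collagen chaperone, fell from 0.0270 to below 0.01. The events of Gucy2c and A730056A06Rik, event 2 of Lrrc4c and event 2 of Lin7a fell from above 0.99 to below 0.01. Events 1 and 2 of Lin7a were near complements and may be 1 change. Pak3 rose from 0.0570 to 0.999, and Fcrl5 and Clec4b1, genes of lymphoid and myeloid receptors, rose from below 0.01 to 0.987 and 0.949.

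In the same comparison, other named events passed for Raver2 knockdown and not for Setd2 knockdown, and each was also called between the knockdowns, a comparison that called 34 events where another split of its libraries called 23. Pdlim5, a protein of the actin cytoskeleton (chromosome 3, 142239590 to 142395696, minus strand), fell in event 5 from 0.999 to below 0.01 (change -0.999 ± 0.0209, SE; adjusted p = 0.00186) and had a mean above 0.99 under Setd2 knockdown. Tlcd1, Pdp1, which activates pyruvate dehydrogenase, and Alg11, an enzyme of N-glycan assembly, fell from means of 0.959 or more to below 0.01. Kcnk13, a potassium channel gene (chromosome 12, 99964499 to 100062682), rose from 0.0281 ± 0.00414 to 0.714 ± 0.00364 (adjusted p = 0.00520). Rhpn1 and event 2 of Slc10a3-ubl4 rose from below 0.01 to above 0.99. A730082K24Rik rose from 0 to 0.504, and event 3 of Cd247, the zeta chain of the T cell receptor complex, from below 0.01 to 0.0581. Event 2 of Rad52, a recombination protein, rose from below 0.01 to 0.0425 ± 0.00173, while event 1 of Rad52 fell to 0.958 ± 0.00173. These Rad52 events were near complements and may be 1 change.

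Across all 4658 events, 113 in 90 genes passed the test for Raver2 knockdown against Ctr (limma, adjusted p under 0.05), 47 higher and 66 lower; 560 had an unadjusted p under 0.05, where 232.9 are expected by chance. The 2 knockdown libraries lay beyond both Ctr libraries in 44.0% of events, where chance gives 33.3%. Of the 113 events, 94 had a fraction below 0.01 or above 0.99 in some library (83.2%, against 57.1% of all events tested), and the count was 75 with only the 4 libraries compared, 10 among mid-range events, 291 without Ctr library 1 and 280 without Ctr library 2. The balance turned without Raver2 library 1 (91 higher and 74 lower) and library 2 (65 and 58). In 1 simulated set of this layout 3 of 11 calls over all events fell on unchanged events. That share is larger than the threshold of 0.05, though 1 set does not measure the rate of false calls. Golim4 passed under 7 of 9 other settings, Nhsl1, Tnip1, Sytl2 and Eif4a2 under 6, Lrrfip1 and Bmp1 under all 9, and Mprip and Picalm under 3, with the direction kept in each.

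The comparison of Setd2 knockdown with Ctr asked which events depend on this histone methyltransferase. Golim4 fell from 0.703 ± 0.0300 (SD, n = 2) to 0.0344 ± 0.0107 (change -0.668 ± 0.0429, SE; limma, adjusted p = 0.0183), and Nhsl1 rose from 0.381 ± 0.0533 to 0.921 ± 0.00481 (adjusted p = 0.0167). Picalm fell to 0.0432, Sytl2 to 0.0609, Lrrfip1 to 0.0242 and Mprip to 0.142, and event 4 of Eif4a2 rose to 0.845 (adjusted p = 0.0254). In the fit of mid-range events alone, Golim4, Nhsl1, Picalm, Sytl2, Lrrfip1 and Mprip passed and Eif4a2 did not (adjusted p = 0.0533). Tnip1, with a mean of 0.860, and both Bmp1 events, with a mean of 0.104, did not pass for Setd2 knockdown over all events (adjusted p = 0.123 and 0.176).

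Among events at the ends of the scale, Kng2, Slc10a7, Fcrl5, Clec4b1, Pak3 and event 1 of Lin7a rose to 0.989 or more under Setd2 knockdown, as did event 3 of Cd209b, a C-type lectin gene, from below 0.01 to above 0.99. Ebf3 fell to 0.00522 ± 0.000218 (change -0.123 ± 0.00177, SE; adjusted p = 0.00246) and Prrx1 to 0.01001 ± 0.00395. Fnbp1, Serpinh1, Gucy2c, Lrrc4c, A730056A06Rik, event 2 of Lin7a, Sphk1, a sphingosine kinase gene, Nrep and Atp6v1c2 all fell to below 0.01. Dusp16, a phosphatase of MAP kinases, rose from 0.742 ± 0.00889 to 0.999 ± 0.00154.

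Further named events passed for Setd2 knockdown and not for Raver2 knockdown, and each was also called between the knockdowns, with the same limit. Event 1 of Ank1, the ankyrin of the red cell membrane skeleton (chromosome 8, 22974844 to 23150497), fell from above 0.99 to 0.00315 ± 0.00446 (change -0.997 ± 0.0209, SE; adjusted p = 0.00246), with a mean above 0.99 under Raver2 knockdown. Ncam1, a neural cell adhesion molecule gene, rose from below 0.01 to 0.0980 ± 0.00574, Scube1 from below 0.01 to 0.0531 ± 0.00479, event 2 of Tlr7, a sensor of single-stranded RNA, from 0.00139 to 0.0415 ± 0.00353, and 4931409K22Rik from below 0.01 to 0.992 ± 0.0114.

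In total, 104 events in 85 genes passed for Setd2 knockdown against Ctr, 41 higher and 63 lower (limma, adjusted p under 0.05), and 540 had an unadjusted p under 0.05 against 232.9 expected. The groups lay apart in 42.5% of events, where chance gives 33.3%. Of these 104, 80 had a library at the end of the scale (76.9%); 6 passed among mid-range events, 279 without Ctr library 1 and 261 without Ctr library 2. With only the 4 libraries compared, limma called 0 events, although 554 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0593, so none of the calls, those of Golim4, Nhsl1 and Aire included, was made in that fit. The balance turned without Setd2 library 2, with 79 higher and 57 lower events. Lrrfip1 passed under 7 of 9 other settings, Golim4, Nhsl1, Picalm, Sytl2 and Eif4a2 under 6 and Mprip under 3, with the direction kept in each.

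**Figure D3:**
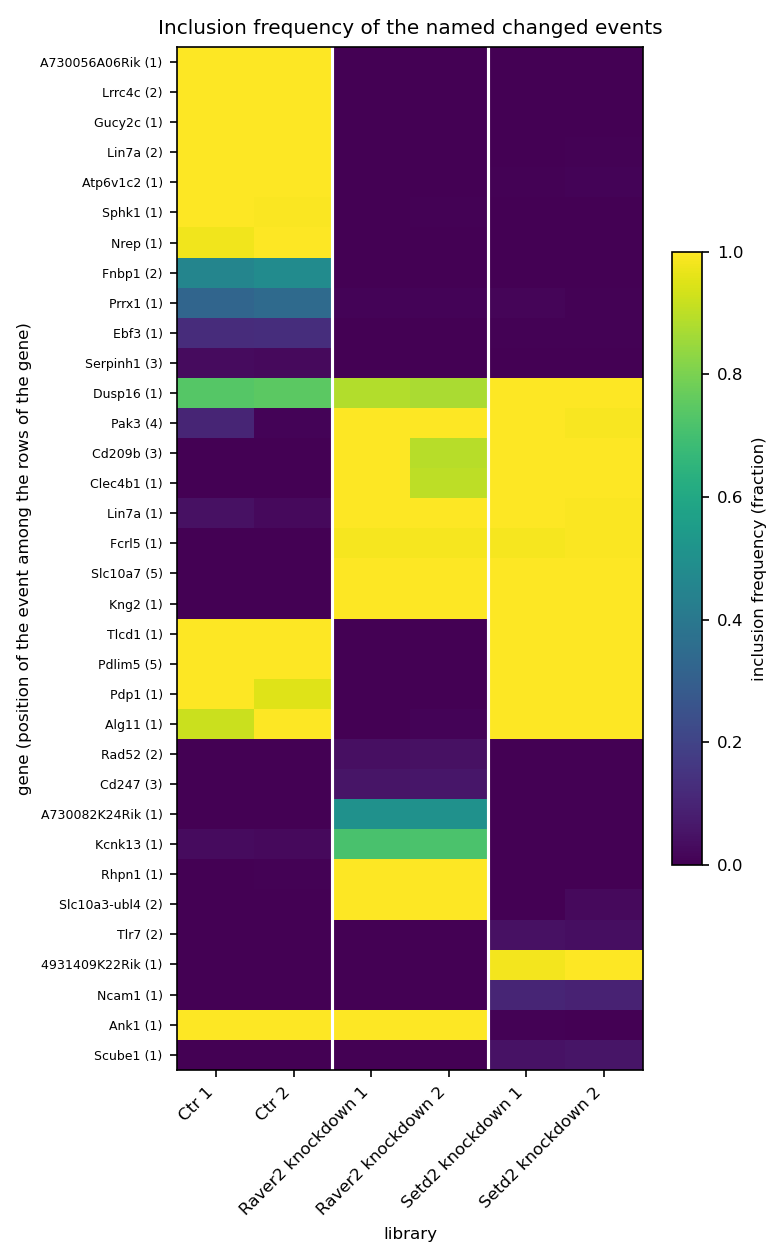
Inclusion frequency (fraction, colour scale from 0 to 1) of the named events that passed in at least 1 comparison with Ctr, one line per event and one column per library, with white lines between the groups of 2 libraries; numbers in parentheses give the order of the event within its gene. Prrx1 has a mean of 0.335 in Ctr against 0.00880 and 0.01001 in the knockdown groups, while Kcnk13 has 0.714 under Raver2 knockdown against 0.0281 in Ctr.

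Many of the events called against Ctr were called in both knockdowns. Of 47 events higher under Raver2 knockdown and 41 higher under Setd2 knockdown, 25 were shared, and of 66 and 63 lower events, 52 were shared; no value for unchanged groups was computed for these counts. Among mid-range events all 5 lower events for Setd2 knockdown (Golim4, Picalm, Sytl2, Lrrfip1 and Mprip) and its single higher event (Nhsl1) were also called for Raver2 knockdown. A single event, C87499, was called in opposite directions, with 0.498 in Ctr, above 0.99 under Raver2 knockdown and below 0.01 under Setd2 knockdown.

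Both comparisons use the same Ctr libraries, so their changes correlate even without an effect. Across mid-range events the Spearman correlation of the changes was 0.675, against a mean of 0.445 and a highest value of 0.501 in 100 simulations of unchanged groups. The covariance was 0.00687 against a simulated 0.00286. With a different Ctr library for each knockdown, the correlation was 0.301 and 0.316 in the possible assignments, above the highest simulated value of 0.0738. Over all events the correlation was 0.554 against a simulated mean of 0.418 and highest value of 0.457, the covariance was 0.0264 against 0.0154, and the correlation with unshared Ctr libraries averaged 0.192. Events are not independent replicates, but the simulations drew each event and library independently. A deviation common to both Ctr libraries would raise the observed correlations and not the simulated ones. The 2 Ctr libraries cannot be split so that each part keeps 2 libraries, so part of the shared calls may come from the shared controls. Both comparisons also use the same spread estimated for each event, which can favour calls in both. With only the 4 libraries compared, 0 events were called for Setd2 knockdown, so no call was shared in those fits.

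**Figure D4:**
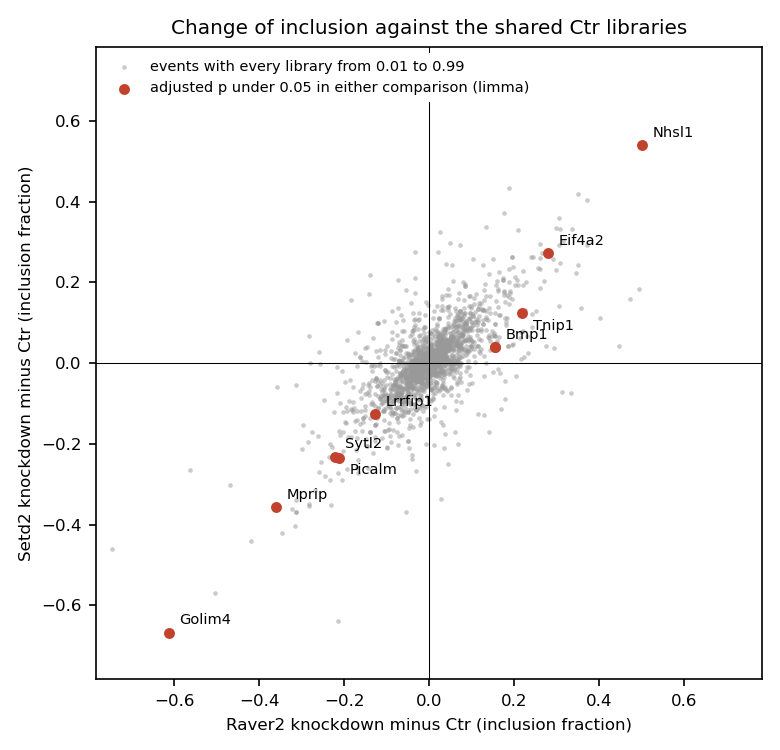
Change of inclusion (fraction) against Ctr under Raver2 knockdown (horizontal) and Setd2 knockdown (vertical) for the 2000 mid-range events (grey); red points passed in either comparison when these events were fitted alone. Golim4 lies at -0.612 and -0.668, Eif4a2 at 0.280 and 0.272, and the Spearman correlation is 0.675, part of which comes from the shared Ctr libraries.

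The 2 hairpins against each target were compared to see whether they moved the same events. With a different Ctr library subtracted from each hairpin, the changes correlated at 0.2005 for Raver2 and 0.161 for Setd2 (Spearman, across all events), and at 0.314 and 0.232 across mid-range events. Between the different targets, a different Ctr library was subtracted from the mean of the 2 libraries of each target, which gave 0.192 and 0.308 on average. Across mid-range events the Setd2 hairpins gave 0.218 and 0.245 in the possible assignments, and the targets gave 0.301 and 0.316. A mean of 2 libraries carries less noise than a single library, so the values for hairpins and targets cannot be ranked. Golim4 had 0.128 and 0.0540 for the Raver2 hairpins and 0.0420 and 0.0269 for the Setd2 hairpins.

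Raver2 and Setd2 knockdown were also compared directly, which does not involve the Ctr libraries. Inclusion was higher under Raver2 knockdown in event 1 of Ank1 (above 0.99 against 0.00315; limma, adjusted p = 0.00294), Kcnk13 (0.714 against 0.00172; adjusted p = 0.00723), Rhpn1, A730082K24Rik, Slc10a3-ubl4, C87499 and event 3 of Cd247. It was also higher in Abi3bp, an extracellular matrix protein gene, with 0.986 against below 0.01, and in Pomgnt2, a glycosyltransferase gene, with 0.897 against below 0.01. Event 3 of Repin1 had 0.931 against 0.00255, and event 2 of Rad52 had 0.0425 against below 0.01. Inclusion was lower under Raver2 knockdown in Tlcd1, Pdlim5, Pdp1, Alg11, Ncam1, 4931409K22Rik, Scube1, Tlr7 and event 1 of Rad52. Smaller differences passed in Ranbp3, a cofactor of nuclear export (0.0226 against 0.0393), Dusp16 (0.879 against 0.999) and Xylb, a xylulose kinase gene (0.870 against above 0.99).

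In this direct comparison 34 events in 29 genes passed, 19 higher and 15 lower under Raver2 knockdown, where the other splits of the same 4 libraries called 23 and 14, and 285 had an unadjusted p under 0.05 against 232.9 expected. The groups lay apart in 33.8% of events, and chance gives 33.3%. Among mid-range events limma called 0, with 107 at an unadjusted p under 0.05 where 100 are expected and a smallest adjusted p of 0.654. Of the 34 events, 31 had a library at the end of the scale (91.2%), and omission of any of the 4 knockdown libraries raised the count, to 67 without Setd2 library 1, 106 without Setd2 library 2 (where the balance turned, with 40 higher and 66 lower), 119 without Raver2 library 1 and 97 without Raver2 library 2.

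Some events were called both against Ctr and between the knockdowns. Raver2 knockdown had 24 such events in 21 genes, 17 higher and 7 lower than Ctr, and Setd2 knockdown had 12 in 10 genes, 8 higher and 4 lower. Chosen after their values were seen, event 1 of Rnf146, a ubiquitin ligase gene, fell from 0.628 ± 0.0181 in Ctr to 0.00223 under Raver2 knockdown and had 0.634 ± 0.0251 under Setd2 knockdown, and event 2 of Nfatc2, a transcription factor of T cell activation, rose from 0.0759 to 0.972 and had 0.0331. Egr3, a transcription factor gene also chosen so, rose from below 0.01 to 0.105 ± 0.0153 under Setd2 knockdown. The Bmp1 events were higher under Raver2 than under Setd2 knockdown over all events (0.220 against 0.104; adjusted p = 0.0315), and did not pass in the fit of mid-range events alone (adjusted p = 0.654). All 34 events called between the knockdowns were among these events.

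Average inclusion over the 4658 events was 0.460 ± 0.00232 in Ctr (SD, n = 2), 0.451 ± 0.000800 under Raver2 knockdown and 0.446 ± 0.00477 under Setd2 knockdown. The changes against Ctr were -0.00840 and -0.0139, and both knockdown libraries lay below both Ctr libraries in each case (exact permutation test, p = 0.333, the smallest that 2 against 2 allows). The mean under Raver2 knockdown minus that under Setd2 knockdown was 0.00546 (exact p = 0.333), with 0.00209 without Setd2 library 2 and 0.00884 without Setd2 library 1, and it turned to -0.00145 among mid-range events, to -0.00223 with at least 3 mid-range libraries and to -1.16e-06 as a median. Over mid-range events the changes were -0.000239 for Raver2 (exact p above 0.99) and 0.00121 for Setd2 (exact p = 0.667), and over the other 2658 events -0.0145 and -0.0252. Inclusion was lower in 51.8% of events under Raver2 knockdown and in 49.3% under Setd2 knockdown, against 47.6%, 49.5% and 52.9% between libraries 1 and 2 within Ctr, Raver2 and Setd2.

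Aire-sensitive genes were represented by 7 genes with 14 events of the 72 listed tissue-restricted antigens. None of their events passed in the 3 comparisons between groups (limma, 0 of 14, also when adjusted over the list alone). Apoc3, another gene of this list, had events in both Ctr libraries and in no knockdown library, so it entered no comparison. Event 2 of Mbp, the myelin basic protein gene, had means of 0.792 ± 0.294 in Ctr (SD, n = 2) and below 0.01 in both knockdowns (adjusted p = 0.180 and 0.168; 0.0498 with both knockdowns together against Ctr, a comparison added after the data were seen), and Calca, the calcitonin gene, had 0.304 ± 0.425 and below 0.01 (adjusted p = 0.712 and 0.699). Fga, a fibrinogen chain gene, had above 0.99, 0.972 and 0.881 in Ctr, Raver2 and Setd2 knockdown. The mean inclusion of Aire-sensitive events minus that of all other events was -0.163 ± 0.0112 in Ctr, -0.162 ± 0.155 under Raver2 knockdown and -0.224 ± 0.0603 under Setd2 knockdown. The change was 0.00146 for Raver2 (exact permutation p above 0.99) and -0.0608 for Setd2 (exact p = 0.333, the smallest possible; -0.103 without Setd2 library 1 and -0.0181 without Setd2 library 2). The value for Raver2 turned to -0.108 without its library 1, to -0.00646 without Ctr library 2 and to -0.0227 with 1 value per gene, and camera called no difference for this list.

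Genes of the splicing machinery held no called event in the 3 comparisons between groups. In the list of SR proteins and other splicing activators, with 24 genes and 49 events, event 1 of Srsf1, a founding SR protein, had 0.119 ± 0.0226 in Ctr (SD, n = 2), 0.384 ± 0.0279 under Raver2 knockdown and 0.391 ± 0.0205 under Setd2 knockdown (limma, adjusted p = 0.101 and 0.0920). Clk1, a kinase of SR proteins, had 0.0665, 0.132 and 0.132, and event 2 of Luc7l had 0.299, 0.560 and 0.558. Among hnRNP, PTB and raver proteins, with 14 genes and 39 events, event 2 of Hnrnpa2b1 had 0.790, 0.710 and 0.713 (adjusted p = 0.153 and 0.157). Among 28 genes with exons linked to PTB or histone methylation, with 54 events, event 1 of Itga6, an integrin of the epithelial basement membrane, had 0.740, 0.928 and 0.940 (adjusted p = 0.105 and 0.0878), and event 1 of Bin1, a membrane-bending protein, had below 0.01, 0.0175 and 0.0181. In the RNA processing list of 10 genes and 13 events, Cpsf7, a cleavage factor, had 0.920, 0.563 and 0.575 (adjusted p = 0.262 and 0.266). None of these lists had a call in those comparisons when adjusted over the list alone. With both knockdowns together against Ctr, Srsf1, Hnrnpa2b1, Itga6 and Bin1 passed in the events named here (limma over all events, adjusted p = 0.0221, 0.0498, 0.0214 and 0.0194).

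Single members of other lists passed in these 3 comparisons. In the thymic epithelial list (9 genes, 25 events) the calls were the 3 Aire events, 2 higher and 1 lower in each knockdown. Of these, events 1 and 3 were near complements and may be 1 change. In the fibroblast list (4 genes, 9 events) event 2 of Fn1, fibronectin, fell from 0.127 ± 0.0110 to below 0.01 in both knockdowns (adjusted p = 0.00676 and 0.00811). In the cytoskeletal list (19 genes, 48 events) event 6 of Pdlim5 rose from 0.869 to 0.989 and 0.992 (adjusted p = 0.0354 and 0.0376), beside the fall of event 5 under Raver2 knockdown. In the apoptosis and DNA damage list (12 genes, 17 events) the Rad52 events passed for Raver2, and event 2 of Cflar, an inhibitor of death receptor signalling, fell from 0.998 to 0.788 for Setd2 (adjusted p = 0.0391) with 0.834 under Raver2 knockdown (adjusted p = 0.0659). Hdac7, a histone deacetylase, rose in event 4 from 0.767 to 0.909 under Setd2 knockdown (chromatin list, 17 genes, 34 events; adjusted p = 0.0493), and Nf2, the merlin tumour suppressor, fell from 0.174 to 0.0101 (epithelial list, 15 genes, 30 events; adjusted p = 0.0276). Eif4a2 was the single call in the translation list (12 genes, 25 events).

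Some lists held no call over all events in the 3 comparisons between groups. In the leukocyte list (8 genes, 10 events) Dntt, the terminal transferase of thymocytes, had 0.0792, 0.141 and 0.132 in Ctr, Raver2 and Setd2 knockdown (adjusted p = 0.0615 and 0.0888; 0.0255 with both knockdowns together against Ctr). In the MHC and antigen processing list (4 genes, 5 events) Cd74, the invariant chain, had 0.124, 0.1005 and 0.0996. In the mitochondrial and metabolic list (7 genes, 10 events) Acly, which makes cytosolic acetyl-CoA, had 0.439, 0.492 and 0.530. Adjusted over the list alone, the counts of higher and lower events for Raver2 became 3 and 5 in the cytoskeletal list, 2 and 2 in the apoptosis list and 2 and 0 in the leukocyte list. For Setd2 they became 2 and 1 in the cytoskeletal list, 1 and 1 in the apoptosis and epithelial lists, 1 and 2 in the fibroblast list and 1 and 0 in the leukocyte list. Between the knockdowns, the thymic epithelial list gained 1 and 1, and all other counts adjusted over the list alone equalled those over all events.

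None of the 15 lists passed camera in the 3 comparisons between groups. The smallest adjusted p was 0.446 for Raver2 against Ctr (leukocyte genes, towards higher inclusion, unadjusted p = 0.0298), 0.339 for Setd2 against Ctr (SR proteins, towards higher inclusion, unadjusted p = 0.0226) and 0.756 for Raver2 against Setd2. With an estimated correlation, the smallest adjusted p was 0.846, 0.725 and 0.823. At an unadjusted p under 0.05 the preset correlation gave 1 list in each comparison with Ctr and 0 between the knockdowns, and the estimated correlation gave 0 in each. The signs of the median change, the mean change and the test differed for 3 lists in Raver2 against Ctr, 5 in Setd2 against Ctr and 3 in Raver2 against Setd2.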

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

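The tests on splits of the libraries, on shared controls, on a batch, on an even fall and on coverage were chosen only after the result was seen; so was that on exons of the epithelial-mesenchymal transition over all events, while its test on mid-range events was written before its result, though after the leading genes were known.

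Genes that no library of a group listed entered no comparison with that group. Both Ctr libraries listed 11 genes that no knockdown library listed (among them 1700034G24Rik, Apoc3, Daw1, Ghrl, Olfr1290, Rbmy, Rgs21, Rgs7, Rnf112 and Tepp), whereas any other pair of libraries shared at most 4 genes absent from the rest. All 4 knockdown libraries listed 4 genes that neither Ctr library listed (6430710C18Rik, C430002N11Rik, Caly and Tex33). From 1 to 10 genes were missing only from a given other pair, so the value of 4 is not unusual among pairs.

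The libraries were regrouped to see how many events other splits call. For Raver2 against Ctr 1 of the 3 splits into 2 and 2, the real one, called 113 events, and the highest of the others called 14. For Setd2 against Ctr it was again 1 of 3 splits, with 104 events against 16, and for Raver2 against Setd2 1 of 3, with 34 events against 23. With both Ctr libraries against the 4 knockdown libraries, 134 events were called, the highest of the 15 possible pairs and the sole 1 to reach that count; the next pair called 21. Among mid-range events that comparison called 54 events, again 1 of 15 pairs, and the next called 1. Neither 3 nor 15 splits can give a share under 0.05.

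Both knockdowns differed from Ctr in many of the same events, as in Golim4, Nhsl1, Picalm and Aire. These were called in each knockdown separately, but no Aire event was called with both knockdowns together against Ctr. Chance values that differ between the Ctr libraries do not, by this measure, account for all of the overlap. With a different Ctr library for each knockdown the correlation of mid-range changes was 0.301, above the highest of 100 simulations without effects, 0.0738. A chance deviation common to both Ctr libraries would stay in this correlation and was not simulated, so it is not addressed. A culture, infection or library batch that separates Ctr from the knockdown libraries would give the same picture, and the 54 mid-range events called for the Ctr pair cannot be told apart from it, because the labels give no batch and any that followed the groups would be confounded with them. A difference in epithelial or mesenchymal state or cell make-up may contribute: of 51 genes with exons known to switch in that transition, the 16 with mid-range events had a median largest t of 2.47, above that of 99.71% of 10000 random lists (median 1.33; 1 called gene, Spag9), and over all events, where Spag9 was not called, 30 genes had 2.05, above 99.67% (median 1.37; 2 called, Arhgef10l and Slc37a2). The score took the absolute t, so it shows no direction towards an epithelial or mesenchymal form. Random lists were matched on the number of events. Another difference between Ctr and the knockdown libraries could give the same score, so the test cannot single out this explanation. The list shares 11 of its 16 genes with other lists, and how many mTECs express is not known here. The sort for MHC class II selects against fibroblasts, but its purity is not known here. Without expression levels the effect of either target, of infection itself and of cell state stays open.

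Mean inclusion was lower in each knockdown library than in both Ctr libraries. None of the explanations tested was argued against. An even fall stays open: over mid-range events the mean change was -0.000239 for Raver2 and 0.00121 for Setd2, but that choice removes events that fell to near 0, and over 2650 events chosen by the Ctr libraries alone it was -0.00624 and -0.00546, where the choice can itself give a change. Thin coverage may contribute, since the lowest share of events below 0.01 in a knockdown library was 20.9% and the highest in a Ctr library 20.6%, and no knockdown library listed more than 2825 genes, where the Ctr libraries listed 2836 and 2857. However, the shares above 0.99 were 12.8% and 11.9% for Raver2 and 13.4% and 14.985% for Setd2 against 13.8% and 12.7% in Ctr, and coverage itself was not measured here, so this stays open as well.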

How the results depend on the processing

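The tests on mid-range events, on events with at least 3 mid-range libraries, on genes with 1 event, on repeated events and on both knockdowns together were chosen only after the result was seen. Of all values computed under other settings for the results below, planned or chosen afterwards, 11 reversed, 43 moved and 94 did neither. In the 94, counts stayed within 1.5 times and shares and correlations within the spread. Mean changes and Aire differences, judged by direction alone, kept their sign there whatever their size. Changes of scale, the variance model, an adjusted p of 0.1 and repeated events left out kept the counts of called events within 1.5 times of 113, 104 and 34, at 108 to 148 for Raver2, 88 to 154 for Setd2 and 23 to 48 between the knockdowns. Depth is unknown, so how far it limits these results cannot be given.

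For Raver2 against Ctr the count fell to 75 with only the 4 libraries compared, to 73 for means from 0.05 to 0.95, to 66 with 1 value per gene, to 10 among mid-range events, to 21 with at least 3 mid-range libraries and to 38 in genes with 1 event. For Setd2 against Ctr the same settings gave 0 (limma, with 554 at an unadjusted p under 0.05), 66, 61, 6, 9 and 37. Between the knockdowns they gave 46, 21, 13, 0 (limma, with 107 at an unadjusted p under 0.05), 5 and 12. Fewer events or libraries enter each of these settings; beyond that the cause was not tested. Leaving out a library gave 123 to 291 for Raver2 (291 without Ctr library 1, 280 without Ctr library 2), 90 to 279 for Setd2 (279 without Ctr library 1, 261 without Ctr library 2) and 67 to 119 between the knockdowns (119 and 97 without Raver2 library 1 or 2, 67 and 106 without Setd2 library 1 or 2). The lone library is then assumed to vary like the other groups, and the cause was not tested.

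The mean change for Raver2 against Ctr kept its sign but ranged from -0.0190 in genes with 1 event to -0.000239 among mid-range events and -8.92e-07 as a median. It reversed for Setd2 against Ctr among mid-range events, to 0.00121, and as a median, to 3.08e-11, and was -0.00325 with at least 3 mid-range libraries and -0.0230 in genes with 1 event. Between the knockdowns it reversed to -0.00145 among mid-range events, -0.00223 with at least 3 mid-range libraries and -1.16e-06 as a median. Leaving out a library kept its sign, with -0.0100457 to -0.00676, -0.0172 to -0.0105 and 0.00209 to 0.00884. The share of lower events for Raver2 moved to 52.7% with 1 value per gene and 53.3% in genes with 1 event, and ranged from 49.9% (without Ctr library 1) to 52.8% with a library left out. For Setd2 it ranged from 48.2% to 51.7% in that way. Between the knockdowns it was 50.7% for means from 0.05 to 0.95, 54.1% with 1 value per gene, 51.0% among mid-range events and 54.4% in genes with 1 event, and ranged from 49.8% (without Setd2 library 2) to 54.6%.

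The change of Aire-sensitive against other events for Raver2 reversed to -0.0227 with 1 value per gene and ranged from -0.108 (without Raver2 library 1) to 0.111 with a library left out, and was -0.00646 without Ctr library 2. For Setd2 it ranged from -0.103 to -0.0181, and between the knockdowns from -0.0473 (without Raver2 library 1) to 0.172. Agreement between the Raver2 hairpins was 0.182 by Pearson correlation, 0.481 with shared Ctr libraries and 0.314 among mid-range events; for Setd2 the latter settings gave 0.420 and 0.232. The correlation of the knockdowns fell to 0.192 with a Ctr library each and was 0.675 among mid-range events. Shared controls raise such values by construction; the other causes were not tested.

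With the replicate number as a block, limma called 0 events between Raver2 and Setd2, with 265 at an unadjusted p under 0.05, and the mean change of 0.00546 is the same by construction. The hairpin numbers do not pair the samples: deviations of libraries with the same number correlated at 0.0146 over all events and 0.0356 among mid-range events, and the block leaves 1 residual degree of freedom.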

Other observations

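The comparison of both knockdowns together with Ctr, and the tests it rests on, were chosen only after the result was seen.

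With the 4 knockdown libraries set against the 2 Ctr libraries, 54 mid-range events passed (limma, adjusted p under 0.05), 27 higher and 27 lower. Among the lower events, some of Fbrsl1, Qsox1 and Gm3286 repeated the values of another event of their gene, so distinct events are fewer and less evenly balanced. The values of the events were seen before they were chosen for mention. Over all events, Spag9, Luc7l, Nelfe, Mov10, event 2 of App and event 1 of Tsc2 did not pass in this comparison, and the other events named here did. In each event named here all 4 knockdown libraries lay beyond both Ctr libraries. Inclusion was higher in the knockdown libraries in Evl, an actin regulator of the Ena/VASP family (0.547 ± 0.0117 in Ctr, SD, n = 2, against 0.825 ± 0.0205, n = 4; adjusted p = 0.00866), in Add3, an adducin of the membrane skeleton (0.242 against 0.551; adjusted p = 0.0143), in Ablim1, an actin-binding LIM protein (0.831 against 0.919), and in event 1 of Itga6 (0.740 against 0.934; adjusted p = 0.0149). It was lower in event 2 of Spag9, a scaffold of JNK signalling (0.527 against 0.265).

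Further events passed in the same comparison. Inclusion of event 1 of Srsf1 was higher in the knockdown libraries (0.119 ± 0.0226, SD, n = 2, against 0.387 ± 0.0204, n = 4; limma, adjusted p = 0.0139), as was that of Nxf1, the mRNA export receptor (0.152 against 0.324; adjusted p = 0.0288), of event 2 of Luc7l, a component of the U1 snRNP (0.299 against 0.559), and of Nelfe, a subunit of the negative elongation factor (0.239 against 0.440). Mov10, an RNA helicase, was lower (0.366 against 0.178). Event 2 of App, the amyloid precursor protein gene, was lower (0.507 against 0.267) and event 2 of its relative Aplp2 higher (0.664 against 0.880), Tsc2, which restrains mTOR signalling, was lower in event 1 (0.359 against 0.168), and event 2 of Pkib, an inhibitor of protein kinase A, was higher (0.0299 against 0.417; adjusted p = 0.0138). These differences set Ctr apart from both knockdowns, and a shared effect of the targets may be involved, but a culture or library batch would give the same 54 events, and the data do not tell these apart.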
